A study of Homo sapiens with 12 samples.

How the data were processed

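Total RNA of EA.hy926 cells had been isolated with an RNeasy kit and hybridised as biotin-labelled target to Affymetrix whole-transcript arrays, per the labels' protocols. Cells were grown in medium with 10% fetal calf serum, and the medium was changed 24 h before treatment. The deposited values are log2 expression values per probe set, made by the authors with RMA (robust multi-array averaging) in Partek 6.5, per the submitters' processing notes. Settings of RMA, such as the background correction, were not given in the sources used here. No background signal or detection call per probe set was used here, so the level at which a gene becomes detectable is unknown.

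The table held 33297 probe sets on 12 arrays, and all columns were matched to samples by their labels. Gene names came from an annotation table of the array and were checked by Entrez identifier against the RefSeq genes of GRCh38.p14, where 19429 of 19460 identifiers were found. Of the probe sets, 19460 had 1 gene symbol, 1754 had several and 12083 were not listed with a gene. Genes were named only from probe sets with 1 symbol, and for the 769 genes with more than 1 probe set the brightest by mean over all arrays was used, which gave 18417 genes. List members without such a probe set were not analysed here, and some items are not reported here. No further normalization and no filter on dim genes was applied. Probe sets of closely related genes, such as the histones, can share sequence, so values of single histone genes are uncertain.

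Samples were grouped by the folate level and treatment in the labels, with 3 biological replicates in each of 4 groups. One linear model with a mean per group was fitted to all 12 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes, 8 residual degrees of freedom), and 5 contrasts were tested: pemetrexed in Hi cells, pemetrexed in Lo cells, low folate in control cells, low folate in treated cells, and the interaction, which is the response of Lo cells minus that of Hi cells. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Errors printed after ± with a log2 change are standard errors of the model. Changes are treated minus control or Lo minus Hi. The p-values measure the spread between biological replicates of 1 cell line. Lo cells were a separately adapted culture, so the low folate contrasts also hold any other difference between the Lo and Hi cultures.

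A total of 25 gene lists was tested with limma's camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the data and with fry. With the estimated correlation 3 of the 12 lists called in treated Lo cells held (p53 targets, the amino acid and ATF4 response and immediate early genes), 2 of 11 in the comparison of treated cells and 2 of 11 in the interaction (in both the p53 targets and the amino acid and ATF4 response), and 0 for Hi cells and for control cells. Without the 2 arrays labelled replicate 3 of the controls, 1 list held in each of these 3 comparisons, the p53 targets, and 0 in the others. Fry with all 12 arrays called 14, 14 and 12 lists in these 3 comparisons, and 0 for Hi cells and for control cells. Lists covered folate and one-carbon metabolism, de novo purine synthesis and salvage, pyrimidine and deoxynucleotide metabolism, p53 targets, S phase and DNA replication, G2 and mitosis, replication-dependent histones, cytokines and chemokines, adhesion molecules, NF-kB targets and feedback, interferon-stimulated genes, prostanoid and leukotriene metabolism, complement and regulators, coagulation and fibrinolysis, endothelial identity, epithelial and lung carcinoma markers, fibroblast and smooth muscle markers, leukocyte markers, amino acid and ATF4 response, NRF2 and oxidative stress, cholesterol synthesis, hypoxia and glycolysis, matrix proteases and inhibitors, immediate early genes and cytosolic ribosomal proteins.

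The groups, contrasts, thresholds, gene lists and the rule for named genes were set before the data were examined. The text names, per contrast, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups do not overlap (for the interaction, among called genes). It also names up to 4 members of each list with the smallest p among called ones, which may be left out for lists with no shift, and a fixed set of genes of folate metabolism and inflammation whatever their p. One set of results, without the arrays labelled Hi control replicate 3 and Lo control replicate 3, was added after the data were seen, and it also supplied the genes named for control cells. In these 10 arrays the deviations from the group means of all 13 same-numbered pairs correlated above 0.1 across genes (0.115 to 0.543). For 8 of the 10 arrays the best match carried the same number. The pairs are not independent checks, since the deviations of the 2 controls left in a group mirror each other. Arrays numbered 2 and 3 also correlated across numbers, up to 0.439 for Hi pemetrexed replicate 3 with Lo control replicate 2. That the replicate numbers pair the arrays was therefore an assumption, and the labels name nothing that same-numbered cultures share. On this assumption the replicate number was added as a block to the fit without the 2 arrays, also after the data were seen.

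The steps were tested on simulated data with the real means and spreads. All arrays of a group were drawn around a common mean, so no simulated array lay with another group. Of 100 genes changed 1.5-fold and 100 changed 2-fold, limma recovered 89 and 99 for pemetrexed in Lo cells, 89 and 99 for low folate in treated cells and 44 and 92 for the interaction, over 18417 genes. Without the 2 arrays it recovered 85 and 100 for low folate in control cells. A shift of 0.3 log2 units given to the cytokine list was found by camera in every contrast, and at most 1 other list was called. The simulated genes were drawn independently, so this does not test false calls of camera where genes of a list are correlated.

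Alternatives were a block for the replicate number, 2 filters on dim genes, the mean of a gene's probe sets, every probe set as its own unit, quantile normalization, median centring, a fit on only the arrays compared, a variance trend with robust moderation, no moderation, array weights, stricter thresholds, and leaving out each array. Figures were drawn with matplotlib 3.10.9.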

Results

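Gene expression was measured in EA.hy926 cells, a human line made by fusing umbilical vein endothelial cells with the A549 lung carcinoma line. One set of cultures was kept in M199 medium with 9 uM folic acid (Hi cells), and a parallel set was adapted to the 23 nM folic acid of the unsupplemented medium (Lo cells). Confluent cultures of both kinds were exposed to 0.5 uM pemetrexed for 48 h or left as controls. Pemetrexed is an antifolate that inhibits thymidylate synthase (TYMS) and the purine synthesis enzyme GART, among others. The 4 groups held 3 biological replicates each, and total RNA of every replicate was hybridised to 1 array, 12 in all. The array medians lay between 7.24 and 7.33 on the log2 scale, and the number of arrays limits the precision of every comparison.

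The arrays separated by folate level, and the Lo arrays also by treatment, with 2 controls out of place. The first principal component held 61.1% of the variance. All 3 Hi pemetrexed arrays and 2 of the Hi controls scored from -20.1 to -17.8 on it, the Lo controls labelled replicates 1 and 2 scored 7.18 and 6.75, and the Lo pemetrexed arrays scored from 30.4 to 32.2. The array labelled Hi control replicate 3 scored 8.94, beside the Lo controls, and the array labelled Lo control replicate 3 scored -19.3, among the Hi arrays. Across genes, which are not independent replicates, the former correlated on average at r = 0.993 with the other Hi controls. With the arrays labelled Lo control, the latter among them, its average was r = 0.995. The latter correlated at r = 0.996 with the Hi pemetrexed arrays and at r = 0.994 with the other Lo controls. Both arrays kept their labels, and the count of genes called in each comparison is also given without them, an alternative added after the data were seen.

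**Figure D1:**
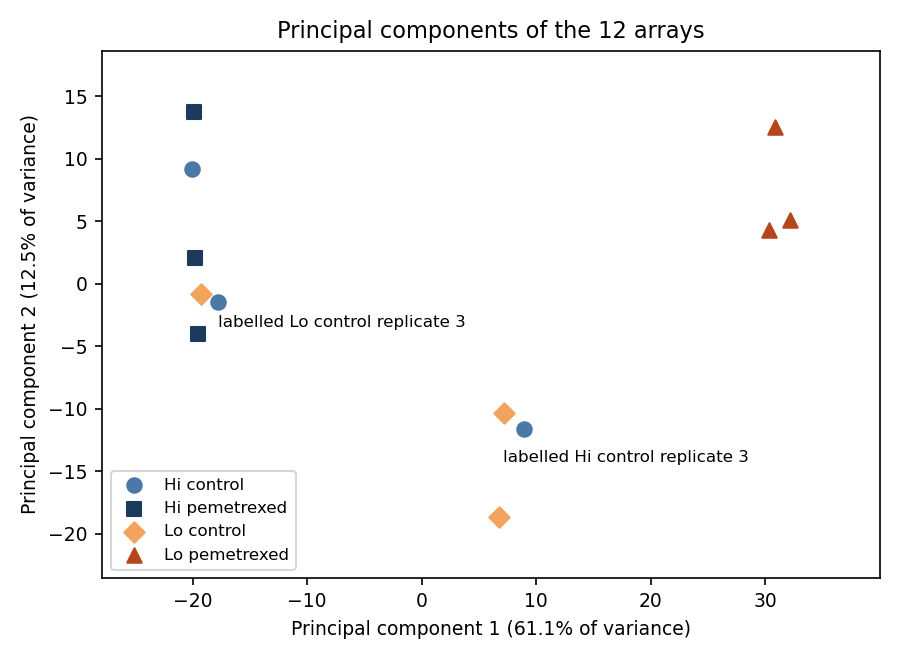
Scores of the 12 arrays on the first and second principal components of 18417 genes, in arbitrary units, with the share of variance on each axis and 1 point per array. The array labelled Hi control replicate 3 (8.94 on the first component) lies with the arrays labelled Lo control replicates 1 and 2. The array labelled Lo control replicate 3 (-19.3) lies with the Hi arrays.

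Whether pemetrexed altered expression in folate-restricted cells was examined by Lo pemetrexed against Lo control arrays. Genes of cell division fell together in treated Lo cells. The mitotic kinase PLK1 changed by -2.44 ± 0.12 (SE) on the log2 scale, and the spindle checkpoint kinase BUB1 by -1.92 ± 0.12. The mitotic kinesin KIF15 (-2.25 ± 0.22), PRR11 (-2.16 ± 0.14), the midzone protein PRC1 (-2.11 ± 0.15), the centromere protein CENPI (-1.95 ± 0.13) and SGO2 (-1.88 ± 0.12), a protector of centromeric cohesion, also fell. The largest fall was that of H2BC14, a histone H2B gene, at -2.90 ± 0.13 (limma, Benjamini-Hochberg adjusted p = 3.63e-07), and for all of these genes every treated array lay below every control array. Of 33 measured G2 and mitosis genes, 30 fell and 0 rose (31 fell adjusted over the list alone), with a median of -1.18. For the mitosis list camera gave adjusted p = 7.5e-42, and adjusted p = 0.054 with an estimated correlation. Of 35 S phase and DNA replication genes, 24 fell (27 adjusted over the list alone), with a median of -0.74. For the S phase list camera gave adjusted p = 1.75e-25, and adjusted p = 0.0794 with an estimated correlation. Members that fell included the replicative helicase subunits MCM6 (-1.68 ± 0.13) and MCM5 (-1.03 ± 0.09), GINS2 (-1.49 ± 0.12) and the clamp loader subunit RFC4 (-1.26 ± 0.10). Of 15 replication-dependent histone genes, 9 fell (10 fell and 2 rose adjusted over the list alone), including H3C2 -1.24 ± 0.17, H2BC4 -0.96 ± 0.14, H2BC8 -0.68 ± 0.10 and H1-2 -0.72 ± 0.13. For the histone list camera gave adjusted p = 3.36e-05, and adjusted p = 0.0537 with an estimated correlation. Of 22 genes of pyrimidine and deoxynucleotide metabolism, 6 fell and 1 rose (10 and 1 adjusted over the list alone). For the pyrimidine list camera gave adjusted p = 0.000606, and adjusted p = 0.239 with an estimated correlation. The uracil glycosylase UNG (-1.04 ± 0.14) and the ribonucleotide reductase subunits RRM1 (-0.75 ± 0.14) and RRM2 (-1.06 ± 0.21) were lower, and the uridine phosphorylase UPP1 was higher (0.81 ± 0.09).

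Genes of the p53 and amino acid stress responses were among those that rose in treated Lo cells. Of 33 measured p53 targets, 21 rose and 0 fell (25 rose adjusted over the list alone), with a median of 0.49. For the p53 list camera gave adjusted p = 4.01e-20, and adjusted p = 0.0356 with an estimated correlation. The cell cycle inhibitor CDKN1A rose by 0.71 ± 0.09, GADD45A by 1.23 ± 0.11, SERTAD1 by 0.99 ± 0.08, the phosphatase gene PPM1D by 0.94 ± 0.11 and SESN2 by 0.89 ± 0.08. Of 24 genes of the amino acid and ATF4 response, 11 rose (15 adjusted over the list alone). For the ATF4 list camera gave adjusted p = 3.88e-09, and adjusted p = 0.0246 with an estimated correlation. Members that rose included the stress transcription factor DDIT3 (2.06 ± 0.24), ATF3 (1.10 ± 0.11) and the amino acid transporter subunit SLC3A2 (0.72 ± 0.10). Of 19 immediate early genes, 8 rose (9 adjusted over the list alone). For the immediate early list camera gave adjusted p = 8.11e-09, and adjusted p = 0.0488 with an estimated correlation. Members that rose included EGR1 (2.04 ± 0.28), FOSB (1.23 ± 0.10), FOS (1.09 ± 0.13) and KLF4 (0.64 ± 0.06). ACTBL2, an actin-like gene, rose by 2.10 ± 0.18, the lipid transporter ABCA12 by 2.10 ± 0.41 and the proton pump subunit ATP6V0D2 by 2.67 ± 0.70, the largest rise with all arrays. In the fit without both arrays out of place the ATF4 and immediate early lists had camera adjusted p = 0.0753 and 0.0881 with an estimated correlation, and the p53 list 0.0183.

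Some cytokine and NF-kB genes rose in treated Lo cells, while most members of these lists did not pass the test. Of 35 measured cytokines and chemokines, 9 rose and 1 fell (11 and 1 adjusted over the list alone). For the cytokine list camera gave adjusted p = 0.000627, and adjusted p = 0.192 with an estimated correlation. The cytokine gene IL1B rose by 2.08 ± 0.53, and IL33 (1.14 ± 0.12), IL32 (1.17 ± 0.14), IL11 (1.21 ± 0.17) and LIF (1.36 ± 0.20) rose as well, with IL1RL1, the receptor gene of interleukin 33, at 2.05 ± 0.50. The monocyte chemokine CCL2 was the 1 that fell, at -0.64 ± 0.12 (limma, Benjamini-Hochberg adjusted p = 0.00352). IL6 (0.75 ± 0.31, limma adjusted p = 0.16), CXCL8 (1.13 ± 0.38, adjusted p = 0.0778) and the cyclooxygenase gene PTGS2 (1.02 ± 0.34, adjusted p = 0.0811) did not pass the Benjamini-Hochberg threshold with all 12 arrays. Without the 2 arrays out of place, IL6 rose by 0.42 ± 0.09, CXCL8 by 0.73 ± 0.21 and PTGS2 by 0.63 ± 0.12 (limma, Benjamini-Hochberg adjusted p = 0.0102, 0.0418 and 0.00469). Of 21 NF-kB targets and feedback genes, 7 rose and 0 fell, both over all genes and adjusted over the list alone. For the NF-kB list camera gave adjusted p = 0.0101, and adjusted p = 0.197 with an estimated correlation. Members that rose included the feedback inhibitor TNFAIP3 (2.27 ± 0.51), TRAF1 (1.72 ± 0.09), NFKB2 (1.18 ± 0.11), RELB (0.71 ± 0.13) and SOD2 (0.56 ± 0.11). Of 34 interferon-stimulated genes, 3 rose on either adjustment, over all genes or adjusted over the list alone: IRF7 0.75 ± 0.14, OAS3 0.54 ± 0.10 and OAS1 0.36 ± 0.09. The list had a median of 0.33 (camera adjusted p = 0.000627, and adjusted p = 0.538 with an estimated correlation), and without the array labelled Lo control replicate 3 its camera adjusted p was 0.0786.

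Most adhesion and endothelial genes did not pass the test in Lo cells, and of those that did all but ICAM1 fell. Of 22 measured adhesion molecules, 1 rose and 4 fell (2 and 7 adjusted over the list alone). For the adhesion list camera gave adjusted p = 0.012, and adjusted p = 0.101 with an estimated correlation. The leukocyte adhesion receptor ICAM1 rose by 0.75 ± 0.12, while P-selectin (SELP, -0.82 ± 0.09), ICAM2 (-0.28 ± 0.07) and the junctional cadherin CDH5 (-0.42 ± 0.12) fell. VCAM1 (0.00 ± 0.08) and E-selectin (SELE, 0.00 ± 0.08) did not pass the test. Of 25 endothelial identity genes, 6 fell and 0 rose (7 fell adjusted over the list alone), with a median of -0.30. For the endothelial list camera gave adjusted p = 0.000378, and adjusted p = 0.239 with an estimated correlation. Members that fell included EGFL7 (-0.75 ± 0.12), the transcription factor ERG (-0.69 ± 0.11), the angiopoietin receptor TEK (-0.65 ± 0.09) and MMRN2 (-0.61 ± 0.15). NOS3, the endothelial nitric oxide synthase gene, stood at 0.00 ± 0.17 and did not pass.

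The pemetrexed targets TYMS and GART and the folate carriers SLC19A1 and FOLR1 were not among the genes called in Lo cells with all 12 arrays. TYMS (-0.31 ± 0.13), GART (0.05 ± 0.11), the purine synthesis gene ATIC (-0.04 ± 0.11), SLC19A1 (-0.01 ± 0.08) and FOLR1 (0.13 ± 0.07) and the polyglutamate synthase FPGS (-0.04 ± 0.09) did not pass the test. Without both arrays out of place and with the replicate number as a block TYMS passed, at -0.36 ± 0.10 (limma adjusted p = 0.0220). GGH, the gene of the hydrolase that removes glutamates from folates, fell by 0.70 ± 0.13. Of 28 genes of folate and one-carbon metabolism, 3 rose and 3 fell, the same numbers as adjusted over the list alone, including MTHFD2 (0.75 ± 0.16) and SHMT1 (-0.90 ± 0.14). Camera called no shift of the lists of folate and one-carbon metabolism (-0.01), de novo purine synthesis and salvage (0.01), prostanoid and leukotriene metabolism (0.04), complement and regulators (0.08), coagulation and fibrinolysis (-0.14), epithelial and lung carcinoma markers (0.01), fibroblast and smooth muscle markers (0.05), leukocyte markers (0.09), NRF2 and oxidative stress (-0.05), cholesterol synthesis (-0.01), hypoxia and glycolysis (0.00), matrix proteases and inhibitors (0.03) and cytosolic ribosomal proteins (0.00), given with their median log2 changes.

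In total 1978 of 18417 genes passed limma's test between treated and control Lo arrays, 1031 higher and 947 lower, and 229 of them changed at least 2-fold (106 higher, 123 lower). With the 2 arrays out of place left out, 2018 genes passed (181 changed at least 2-fold, 65 higher and 116 lower), and 1629 passed in both fits, each in the same direction. The count was 1210 without the array labelled Lo control replicate 3, 1282 without Lo pemetrexed replicate 1 and 1170 without Lo pemetrexed replicate 3. ATP6V0D2, IL1B and IL1RL1 lost the call without the array labelled Lo control replicate 3 or without any 1 of the Lo pemetrexed arrays (limma adjusted p up to 0.104, 0.0890 and 0.0678). ICAM2, MMRN2 and OAS1 lost it without that control or Lo pemetrexed replicate 3 (up to 0.0804, 0.0846 and 0.0783), and CDH5 without any Lo control, Lo pemetrexed replicates 2 or 3, Hi control replicate 2 or Hi pemetrexed replicate 2 (up to 0.171). In the fit without both arrays out of place the rises were smaller, at 1.89 ± 0.24 for ATP6V0D2, 1.61 ± 0.11 for TNFAIP3, 1.47 ± 0.15 for IL1B and 1.46 ± 0.10 for IL1RL1. In it ICAM2 and OAS1 did not pass (limma adjusted p = 0.055 and 0.0525). With the replicate number added as a block to that fit 3385 genes passed, among them TYMS and OAS1, the latter at 0.28 ± 0.09 with limma adjusted p = 0.0485. The interferon list lost its call there (camera adjusted p = 0.213).

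**Figure D2:**
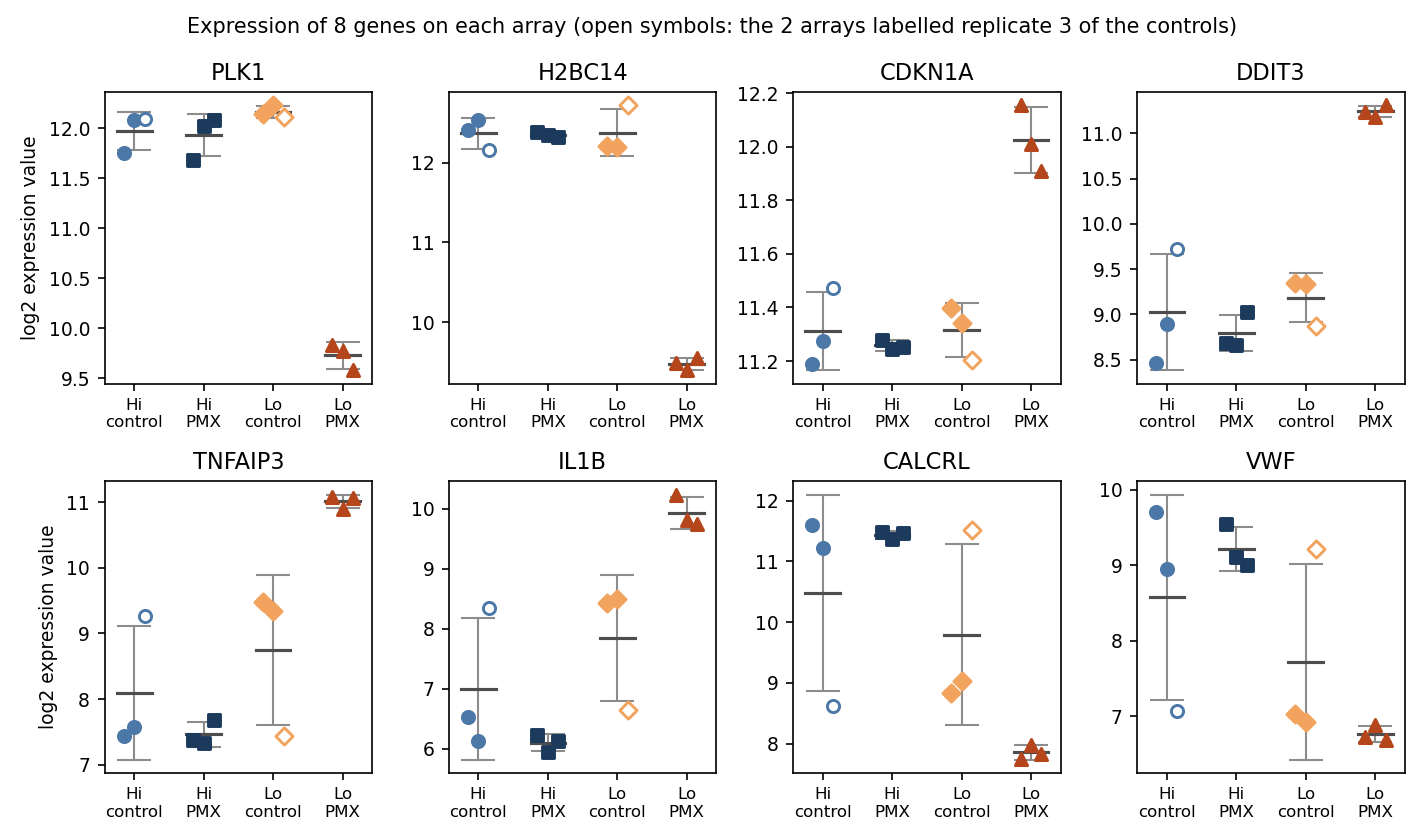
Log2 expression values of 8 genes on each of the 12 arrays, 1 symbol per array, with the group mean (dark line) and SD (grey bars, n = 3), where PMX is pemetrexed and open symbols are the 2 arrays labelled replicate 3 of the controls. PLK1 and H2BC14 lie lower and CDKN1A, DDIT3, TNFAIP3 and IL1B higher on all 3 Lo pemetrexed arrays than on any other array, and for CALCRL and VWF the open symbols lie with the other folate level.

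The same treatment was examined in folate-replete cells by Hi pemetrexed against Hi control arrays. None of the genes that moved in Lo cells passed the test there. PLK1 stood at -0.04 ± 0.12, H2BC14 at -0.02 ± 0.13, CDKN1A at -0.05 ± 0.09, DDIT3 at -0.23 ± 0.24, ICAM1 at 0.05 ± 0.12 and CCL2 at 0.01 ± 0.12. Of the genes named in advance, CXCL8 (-0.60 ± 0.38) and PTGS2 (-0.52 ± 0.34) had the largest differences. In the fit without both arrays out of place they were at -0.17 ± 0.21 and -0.10 ± 0.12, and IL6 at 0.14 ± 0.09. With all arrays TYMS (0.03 ± 0.13), GART (-0.01 ± 0.11), ATIC (-0.13 ± 0.11), GGH (0.04 ± 0.13), IL6 (-0.27 ± 0.31), VCAM1 (0.11 ± 0.08) and SELE (0.04 ± 0.08) were closer to 0. So were NOS3 (0.16 ± 0.17), FOLR1 (0.07 ± 0.07), SLC19A1 (0.01 ± 0.08) and FPGS (0.10 ± 0.09). Limma called 0 of 18417 genes, and 266 had an unadjusted p under 0.05, where 921 are expected by chance. Limma without variance moderation also called 0, as did the fit without the 2 arrays (335 at an unadjusted p under 0.05). Counts under the number expected by chance are not themselves evidence that an effect is absent. The median 95% confidence interval spanned 1.15-fold to either side. In simulated data for this comparison 78 of 100 genes changed 1.5-fold and 100 of 100 changed 2-fold were recovered. No simulated array lay out of place, unlike the array labelled Hi control replicate 3 here. In data simulated for the fit without the 2 arrays 91 and 100 were recovered. Camera placed 3 lists past its threshold with 0 members called, over all genes or adjusted over the list alone. The number of lists ran from 1 to 9 when single arrays were left out. The interferon-stimulated genes had a median of -0.13 (camera adjusted p = 9.67e-05, and adjusted p = 0.694 with an estimated correlation). G2 and mitosis had a median of -0.10 (camera adjusted p = 0.00544, and adjusted p = 0.716 with an estimated correlation). Replication-dependent histones had a median of 0.12 (camera adjusted p = 0.0303, and adjusted p = 0.694 with an estimated correlation). The interferon and mitosis lists lost the call without the array labelled Hi control replicate 3 (camera adjusted p = 0.958 for both). The mitosis list lost it also without Hi control replicate 2 or Hi pemetrexed replicate 1, in the latter case with its direction reversed (camera adjusted p = 0.219). The histone list lost it without Hi control replicates 1 or 2 or Hi pemetrexed replicates 1 or 3 (up to 0.2005). In the fit without both arrays out of place camera called the histones (median 0.15, camera adjusted p = 0.00206, and adjusted p = 0.846 with an estimated correlation) and the cytosolic ribosomal proteins (median 0.07, camera adjusted p = 0.00554, and adjusted p = 0.98 with an estimated correlation).

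The difference between the responses of Lo and Hi cells was tested directly as an interaction. Among inflammatory genes the response in Lo cells exceeded that in Hi cells by 2.98 ± 0.75 log2 units for IL1B, 2.90 ± 0.72 for TNFAIP3 and 2.83 ± 0.71 for IL1RL1. Among division genes the difference was -2.40 ± 0.17 for PLK1, -2.22 ± 0.20 for PRR11, -2.22 ± 0.31 for KIF15, -2.02 ± 0.22 for PRC1, -1.93 ± 0.18 for CENPI and -1.88 ± 0.21 for the kinetochore gene SPC25. The histone genes H2BC14 (-2.88 ± 0.18) and H2BC3 (-2.02 ± 0.30) also had negative interactions. ATP6V0D2 (3.92 ± 1.00), ABCA12 (2.52 ± 0.58), EGR1 (2.42 ± 0.39), the serpin SERPINB7 (2.39 ± 0.57) and ACTBL2 (2.36 ± 0.26) had the other large positive ones. Of the genes named in advance, CDKN1A (0.76 ± 0.13), ICAM1 (0.71 ± 0.17), CCL2 (-0.65 ± 0.16) and GGH (-0.74 ± 0.19) passed. IL6 (1.02 ± 0.44), CXCL8 (1.73 ± 0.53), PTGS2 (1.55 ± 0.49) and TYMS (-0.34 ± 0.19) did not pass. In the fit without both arrays out of place the interaction was 0.27 ± 0.13 for IL6 and 0.91 ± 0.29 for CXCL8. GART (0.06 ± 0.15), ATIC (0.09 ± 0.15), FOLR1 (0.05 ± 0.10), SLC19A1 (-0.03 ± 0.11), FPGS (-0.13 ± 0.13), VCAM1 (-0.11 ± 0.11), SELE (-0.04 ± 0.11) and NOS3 (-0.16 ± 0.25) did not either. Limma called 886 genes, 474 with the more positive response in Lo cells and 412 with the more negative one. With both arrays out of place left out 767 passed, 605 of them in both fits and in the same direction. The interactions of the large risers were smaller in that fit, at 2.24 ± 0.34 for ATP6V0D2, 1.70 ± 0.22 for IL1B, 1.66 ± 0.16 for TNFAIP3, 1.60 ± 0.14 for IL1RL1, 1.52 ± 0.14 for ABCA12 and 1.42 ± 0.17 for SERPINB7. All 6 still passed there, and PTGS2 (0.73 ± 0.17) passed too (limma adjusted p = 0.0326 for PTGS2 and at most 0.0032 for the 6). The count was 443, 568 and 584 without Lo pemetrexed replicates 3, 1 and 2, 506 and 539 without Hi pemetrexed replicates 2 and 3, and 572 without the array labelled Lo control replicate 3. Those 6 genes each lost the call without any 1 of the 6 pemetrexed arrays, and all but ABCA12 also without the array labelled Lo control replicate 3, or for TNFAIP3 Hi control replicate 3 (limma adjusted p up to 0.109 for ATP6V0D2). CCL2 lost it without Lo pemetrexed replicates 2 or 3, Hi pemetrexed replicates 1 or 2 or replicates 1 or 2 of either control (up to 0.108). ICAM1 lost it without any Lo pemetrexed array, Lo controls 1 or 2, Hi control 2 or Hi pemetrexed replicates 1 or 3 (up to 0.0807). GGH lost it without any array but Lo control 1, Hi pemetrexed replicate 1 and the array labelled Hi control replicate 3 (up to 0.110). With the replicate number as a block in the fit without both arrays 1738 genes passed, CXCL8 among them (0.91 ± 0.21, limma adjusted p = 0.017).

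By the interaction test 17 of 33 p53 targets responded more positively in Lo cells (24 adjusted over the list alone; camera adjusted p = 3.49e-18, and adjusted p = 0.048 with an estimated correlation). Of the amino acid and ATF4 response, 9 of 24 did so (10 adjusted over the list alone; camera adjusted p = 3.84e-08, and adjusted p = 0.0361 with an estimated correlation). Without both arrays out of place camera gave this list adjusted p = 0.0643 with an estimated correlation. Of the immediate early genes, 8 of 19 did so (also 8 adjusted over the list alone; camera adjusted p = 7.08e-08, and adjusted p = 0.0505 with an estimated correlation). Cytokines and chemokines had 6 more positive and 1 more negative of 35 (11 and 1 adjusted over the list alone; camera adjusted p = 0.000662, and adjusted p = 0.193 with an estimated correlation). Interferon-stimulated genes had 2 more positive of 34 (also 2 adjusted over the list alone; camera adjusted p = 1.21e-05, and adjusted p = 0.349 with an estimated correlation). These members, IRF7 and OAS3, each lost the call without any 1 of the pemetrexed arrays or the array labelled Lo control replicate 3 (limma adjusted p up to 0.103 and 0.0895). Without both arrays out of place OAS3 did not pass (limma adjusted p = 0.056), though it did with the block in that fit (limma adjusted p = 0.0286). In the other direction, 23 of 33 G2 and mitosis genes responded more negatively in Lo cells (30 adjusted over the list alone; camera adjusted p = 1.68e-32, and adjusted p = 0.0985 with an estimated correlation). So did 16 of 35 S phase and DNA replication genes (25 adjusted over the list alone; camera adjusted p = 7.9e-21, and adjusted p = 0.124 with an estimated correlation). Of replication-dependent histones, 7 of 15 did (10 with 3 opposite adjusted over the list alone; camera adjusted p = 1.65e-05, and adjusted p = 0.0505 with an estimated correlation). Pyrimidine and deoxynucleotide metabolism had 2 more negative and 1 more positive of 22 (8 and 1 adjusted over the list alone; camera adjusted p = 0.00412, and adjusted p = 0.307 with an estimated correlation). Endothelial identity had 3 more negative of 25 (5 adjusted over the list alone; camera adjusted p = 0.000199, and adjusted p = 0.292 with an estimated correlation). Adhesion molecules had 2 more negative and 1 more positive of 22 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0247, and adjusted p = 0.139 with an estimated correlation). The adhesion list lost its call without Lo pemetrexed replicate 3, Lo control replicate 1, Hi control replicate 2 or Hi pemetrexed replicate 1 (camera adjusted p up to 0.0565).

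**Figure D3:**
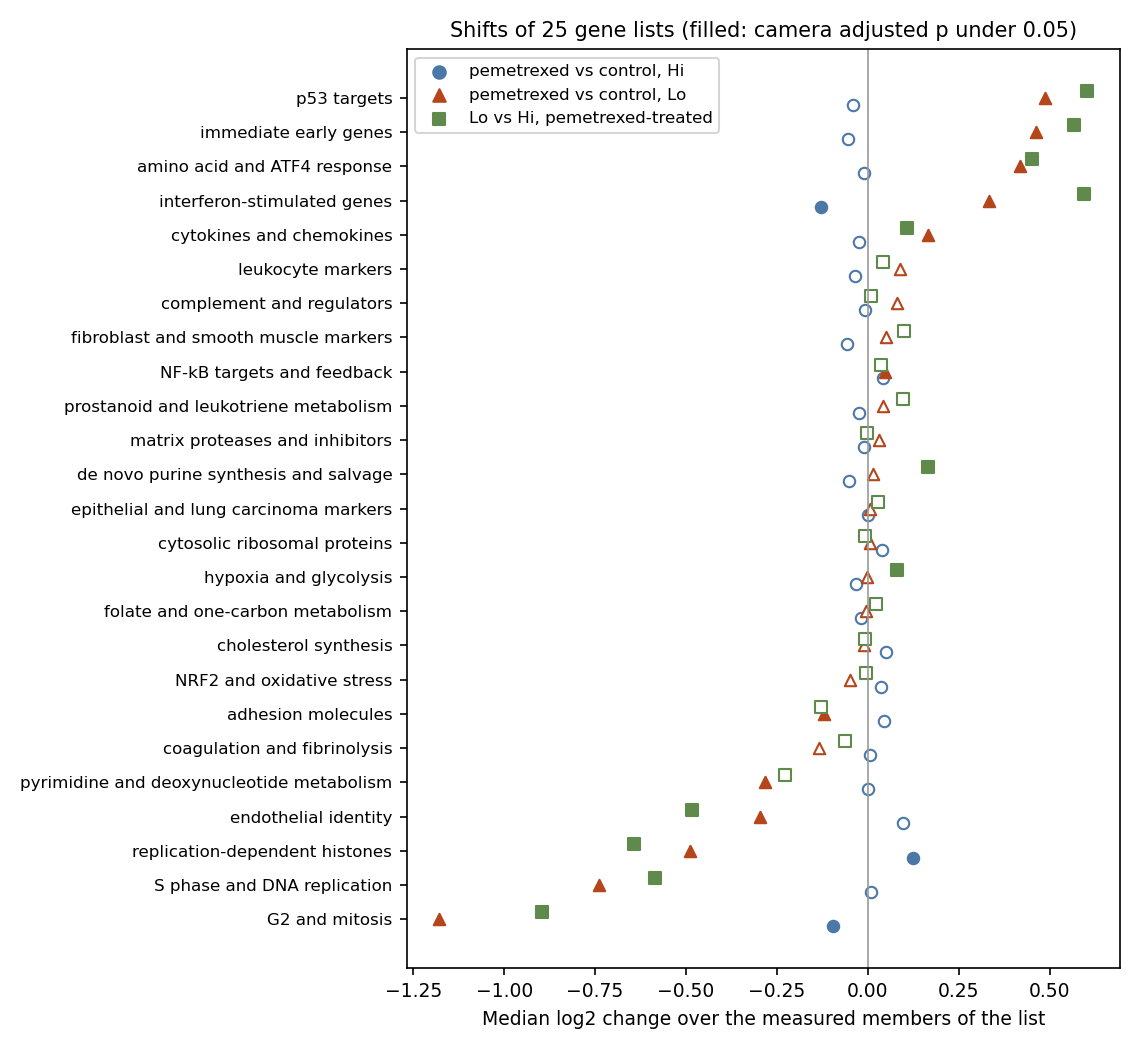
Median log2 change of the measured members of 25 gene lists for pemetrexed against control in Hi cells (circles) and Lo cells (triangles) and for Lo against Hi among treated cells (squares), with filled symbols where the camera adjusted p is under 0.05 at its preset correlation. In Lo cells G2 and mitosis has the lowest median (-1.18) and p53 targets the highest (0.49), and the medians in Hi cells lie between -0.13 and 0.12.

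Lo and Hi cells were also compared with each other under pemetrexed, a comparison of 6 treated arrays in which the controls enter only the estimate of the spread. Of the members that passed the test, most cytokines and interferon-stimulated genes were higher and most endothelial identity genes lower in treated Lo than in treated Hi cells. The enamel matrix gene AMTN was higher by 4.88 ± 1.24, ATP6V0D2 by 4.64 ± 0.70, CLCA2 by 4.30 ± 0.93, IL1B by 3.83 ± 0.53, TNFAIP3 by 3.55 ± 0.51 and IL1RL1 by 3.51 ± 0.50. So were the interleukin 7 receptor IL7R by 3.39 ± 0.60 and SERPINB7 by 3.21 ± 0.40. The adrenomedullin receptor gene CALCRL (-3.58 ± 0.72), multimerin 1 (MMRN1, -3.44 ± 0.66), the ganglioside synthase ST3GAL5 (-3.12 ± 0.58), H2BC14 (-2.87 ± 0.13) and RASGRP3 (-2.82 ± 0.61) were lower. ABCA8 (-2.81 ± 0.50), LRRC70 (-2.72 ± 0.51) and the integrin ITGA10 (-2.47 ± 0.44) were lower as well, and for these 16 genes the arrays of the groups did not overlap. Among genes named in advance CXCL8 (2.12 ± 0.38), PTGS2 (1.99 ± 0.34), IL6 (1.43 ± 0.31), CDKN1A (0.77 ± 0.09) and ICAM1 (0.52 ± 0.12) were higher and GGH (-0.54 ± 0.13) and CCL2 (-0.47 ± 0.12) lower in Lo cells. TYMS (-0.19 ± 0.13), GART (0.18 ± 0.11), ATIC (0.25 ± 0.11), FOLR1 (0.01 ± 0.07), SLC19A1 (0.03 ± 0.08), FPGS (-0.14 ± 0.09), VCAM1 (-0.10 ± 0.08), SELE (-0.03 ± 0.08) and NOS3 (-0.25 ± 0.17) did not pass.

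Of 34 interferon-stimulated genes, 20 were higher and 1 lower in treated Lo than in treated Hi cells (26 and 1 adjusted over the list alone), with a median of 0.59. For the interferon list camera gave adjusted p = 1.37e-07, and adjusted p = 0.299 with an estimated correlation. Examples are the interferon regulatory factor IRF7 (0.84 ± 0.14), OAS3 (0.70 ± 0.10) and ISG15 (0.49 ± 0.10), and the guanylate-binding protein gene GBP2 was the 1 that was lower (-1.04 ± 0.20). Of 25 endothelial identity genes, 12 were lower and 1 higher (13 and 1 adjusted over the list alone), with a median of -0.48. For the endothelial list camera gave adjusted p = 5.04e-05, and adjusted p = 0.214 with an estimated correlation. The lower members included EGFL7 (-1.10 ± 0.12), PECAM1 (-1.09 ± 0.20), ERG (-0.86 ± 0.11) and TEK (-0.66 ± 0.09). Cytokines and chemokines had 14 higher and 3 lower of 35 (15 and 3 adjusted over the list alone; camera adjusted p = 0.00207, and adjusted p = 0.214 with an estimated correlation). LIF (1.73 ± 0.20) and IL11 (1.54 ± 0.17) were among the higher. P53 targets had 26 of 33 higher (30 adjusted over the list alone; camera adjusted p = 1.84e-18, and adjusted p = 0.0447 with an estimated correlation). The amino acid and ATF4 response had 12 of 24 (13 adjusted over the list alone; camera adjusted p = 1.37e-07, and adjusted p = 0.0447 with an estimated correlation). Without both arrays out of place camera gave this list adjusted p = 0.142 with an estimated correlation. Immediate early genes had 12 of 19 (14 adjusted over the list alone). For the immediate early list camera gave adjusted p = 6.03e-07, and adjusted p = 0.0982 with an estimated correlation. G2 and mitosis had 26 of 33 lower (27 adjusted over the list alone; camera adjusted p = 5.51e-19, and adjusted p = 0.214 with an estimated correlation). S phase and DNA replication had 21 of 35 (24 adjusted over the list alone, with 1 higher; camera adjusted p = 3.36e-13, and adjusted p = 0.214 with an estimated correlation). Replication-dependent histones had 9 lower and 3 higher of 15 (10 and 3 adjusted over the list alone). For the histone list camera gave adjusted p = 0.00046, and adjusted p = 0.117 with an estimated correlation. Purine synthesis and salvage had 3 higher and 1 lower of 16 on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0261, and adjusted p = 0.496 with an estimated correlation). Hypoxia and glycolysis had 8 of 23 higher, also 8 adjusted over the list alone (camera adjusted p = 0.0201, and adjusted p = 0.214 with an estimated correlation). VEGFA (1.05 ± 0.10) and the glucose transporter SLC2A1 (1.23 ± 0.21) were among them. Limma called 4107 genes in this comparison, 2079 higher and 2028 lower in Lo cells, and 502 of them differed at least 2-fold. Without the 2 control arrays out of place 5106 passed, and 4106 passed in both fits. ATIC passed only there (limma adjusted p = 0.0382), and NOS3 only with the replicate number as a block in that fit (limma adjusted p = 0.0211). The purine list lost its call without Hi pemetrexed replicates 1 or 2 or Lo pemetrexed replicate 2, and the hypoxia list without the last of these (camera adjusted p up to 0.0829 and 0.0542). CCL2 and GGH lost theirs without Lo pemetrexed replicate 3, and GGH also without Hi pemetrexed replicate 3 (limma, Benjamini-Hochberg adjusted p = 0.0519 and 0.0517).

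Untreated Lo and Hi cells were compared by Lo control against Hi control arrays, where the 2 arrays out of place sit in opposite groups. Lo cells were a separately adapted culture, so an effect of folate cannot be told apart from other differences between the cultures. With all 6 control arrays no gene passed, and the spread within groups was wide: CALCRL differed by -0.69 ± 0.72, VWF by -0.85 ± 0.62 and IL1B by 0.85 ± 0.53. Limma called 0 of 18417 genes, 387 had an unadjusted p under 0.05 where 921 are expected by chance, and limma without variance moderation called 0 as well. In simulated data for this comparison 84 of 100 genes changed 1.5-fold and 100 of 100 changed 2-fold were recovered. No simulated array lay out of place, so these shares do not measure what this comparison, with 2 such arrays, could detect. Camera with its preset correlation placed 6 lists higher in Lo cells, with 0 members called over all genes or adjusted over the list alone. They were G2 and mitosis (median 0.24), S phase and DNA replication (0.17), purine synthesis and salvage (0.08), pyrimidine and deoxynucleotide metabolism (0.07), interferon-stimulated genes (0.10) and folate and one-carbon metabolism (0.04). These had camera adjusted p = 6.79e-20, 5.17e-08, 0.00572, 0.0229, 0.0355 and 0.0395, and none held, with adjusted p = 0.639 or more with an estimated correlation. The S phase list also lost the call without Hi control replicate 1 (camera adjusted p = 0.0789) and the pyrimidine list without that array or Lo control replicate 2 (up to 0.459). The purine and folate lists lost it without Hi controls 1 or 2 or Lo control 2 (up to 0.358 and 0.585). The interferon list lost it without any of these or Lo control 1. Without Lo control 2 the direction of the interferon list was also reversed (camera adjusted p = 0.794).

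Without the 2 arrays, leaving 2 Lo and 2 Hi controls, most endothelial identity genes that passed the test were lower, and most such cytokines and interferon-stimulated genes higher, in untreated Lo cells. These genes were taken by the rule for named genes applied to a fit chosen after the data were seen. The von Willebrand factor gene VWF was lower (-2.36 ± 0.21; limma, Benjamini-Hochberg adjusted p = 4.72e-05). So were CALCRL (-2.48 ± 0.12), MMRN1 (-2.39 ± 0.12), RASGRP3 (-2.16 ± 0.15), ST3GAL5 (-2.10 ± 0.09), the vascular endothelial growth factor receptor KDR (-1.97 ± 0.17), the protease MMP10 (-1.89 ± 0.16) and LRRC70 (-1.86 ± 0.12). AMTN (4.38 ± 0.39), CLCA2 (3.63 ± 0.12), osteopontin (SPP1, 2.67 ± 0.27), CPA4 (2.51 ± 0.36), SULT1B1 (2.46 ± 0.19), ATP6V0D2 (2.40 ± 0.26), DHRS9 (2.36 ± 0.17) and IL7R (2.34 ± 0.19) were higher. Of 25 endothelial identity genes, 7 were lower and 3 higher (10 and 3 adjusted over the list alone). For the endothelial list camera gave adjusted p = 2.27e-05, and adjusted p = 0.368 with an estimated correlation. Examples were EMCN (-1.77 ± 0.10) and ROBO4 (-1.04 ± 0.10). Of 34 interferon-stimulated genes, 11 were higher and 1 lower (17 and 1 adjusted over the list alone). For the interferon list camera gave adjusted p = 1.53e-11, and adjusted p = 0.285 with an estimated correlation. Examples were XAF1 (1.75 ± 0.16), IFI6 (1.32 ± 0.10) and BST2 (1.12 ± 0.11). Of 35 cytokines and chemokines, 7 were higher and 1 lower (8 and 3 adjusted over the list alone). For the cytokine list camera gave adjusted p = 0.0178, and adjusted p = 0.368 with an estimated correlation. Examples were IL1B (2.13 ± 0.17), IL1A (1.07 ± 0.09), IL6 (1.16 ± 0.10) and CXCL8 (1.22 ± 0.23), with TNFSF10 lower (-0.84 ± 0.12). Of 33 G2 and mitosis genes, 10 were higher (18 adjusted over the list alone). For the mitosis list camera gave adjusted p = 1.79e-13, and adjusted p = 0.368 with an estimated correlation. Examples were HMMR (0.78 ± 0.14) and CCNB1 (0.71 ± 0.14). PTGS2 was higher too (1.26 ± 0.13). TYMS (0.23 ± 0.16), GART (0.20 ± 0.13), ATIC (0.35 ± 0.10), GGH (0.32 ± 0.16) and CDKN1A (0.14 ± 0.09) did not pass. ICAM1 (-0.36 ± 0.12), CCL2 (0.37 ± 0.11), VCAM1 (0.04 ± 0.10), SELE (0.13 ± 0.08), NOS3 (-0.33 ± 0.18), FOLR1 (-0.07 ± 0.09), SLC19A1 (0.12 ± 0.09) and FPGS (-0.07 ± 0.11) did not pass either. Limma called 1320 genes in this fit, 676 higher and 644 lower in Lo cells. With the replicate number as a block it called 2422, with ATIC, ICAM1, CCL2 and NOS3 among them (limma adjusted p = 0.00833, 0.0117, 0.00527 and 0.0357).

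The genes that differed by folate level in untreated cells and those changed by pemetrexed in Lo cells overlapped, again without the 2 arrays. The fit without the replicate number as a block was used. Of 1320 and 2018 genes, 495 passed both tests, and 351 of these went the same way. They were 162 higher in both and 189 lower in both, where independent sets would share 35.2 and 37.0. The remaining 144 went opposite ways, 117 of them higher in Lo cells and lower with pemetrexed and 27 the reverse. The number that independent sets would share was not worked out for these. Of the 144, 12 belonged to the S phase and mitosis lists. Both comparisons use the same 2 Lo control arrays with opposite signs, which by itself makes their changes tend to go opposite ways. Across genes, which are not independent replicates, their log2 changes correlated at r = 0.112 with a covariance of 0.00705. Unchanged groups simulated around shared controls, with no pairing by replicate number, gave a mean r of -0.547 and a mean covariance of -0.00654.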

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

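The tests of an exchange of labels, of a mixed sample, of a shift shared by replicate 3 and of the count of calls without the 2 arrays were chosen after the result was seen.

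A total of 886 genes responded differently to pemetrexed in Lo and Hi cells by limma's interaction test. The medians of the difference of log2 changes (Lo minus Hi) over the lists called by camera were 0.55 for p53 targets, 0.46 for the amino acid and ATF4 response, 0.50 for immediate early genes, 0.46 for interferon-stimulated genes and 0.16 for cytokines and chemokines. They were -1.06 for G2 and mitosis, -0.74 for replication-dependent histones, -0.69 for S phase and DNA replication, -0.41 for endothelial identity, -0.34 for pyrimidine and deoxynucleotide metabolism and -0.15 for adhesion molecules. With an estimated correlation 2 of these 11 lists held by camera, the p53 targets and the amino acid and ATF4 response, and without both arrays out of place 1 held, the p53 targets. Single genes with a more positive response in Lo cells were ATP6V0D2 (3.92), IL1B (2.98), TNFAIP3 (2.90), IL1RL1 (2.83), ABCA12 (2.52), EGR1 (2.42), SERPINB7 (2.39), ACTBL2 (2.36), CDKN1A (0.76) and ICAM1 (0.71). Those with a more negative response were H2BC14 (-2.88), PLK1 (-2.40), PRR11 (-2.22), KIF15 (-2.22), H2BC3 (-2.02), PRC1 (-2.02), CENPI (-1.93), SPC25 (-1.88), GGH (-0.74) and CCL2 (-0.65). Without both arrays out of place ATP6V0D2 stood at 2.24, IL1B at 1.70, TNFAIP3 at 1.66, IL1RL1 at 1.60, ABCA12 at 1.52 and SERPINB7 at 1.42.

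Of 13837 probe sets without a single gene name, which entered no comparison of genes, limma called 260 for pemetrexed in Lo cells, 783 for low folate in treated cells and 87 for the interaction. These are 1.88%, 5.66% and 0.629% of them, against 7.61%, 17.7% and 2.45% of the probe sets with 1 gene name.

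Pemetrexed changed 1978 genes in Lo cells and 0 in Hi cells. Without the 2 arrays out of place the counts were 2018 and 0, which argues against those arrays as the cause. Under quantile normalization or median centring the count in Hi cells was 0 in both against at least 1733 in Lo cells. The array medians of the deposited values already lay between 7.24 and 7.33, so further scaling had little to correct. It cannot test the scaling between arrays that the authors had applied. The median within-group SD of the Hi groups without the 2 arrays was 1.05 times that of the Lo groups, which argues against noisier Hi arrays. Over the genes called in Lo cells the slope of the Hi change on the Lo change was -0.00533. A slope of 0 or below had been set beforehand as a sign against a weaker form of the same response. The other 9 splits of the same 5 Hi arrays gave slopes from -0.0772 to 0.0706, a range that holds the real slope. The values argue against a weaker form with a slope well beyond that range, while a weaker form within it stays open. The lower folate of the Lo medium, the difference named by the design, also stays open, as a hypothesis that may account for the pattern.

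The 2 control arrays that lie with the other folate level were weighed against 3 technical explanations. On an axis set by the treated arrays, where the other Hi controls average 0 and the other Lo controls 1, the array labelled Hi control replicate 3 lay at 1.05 and the array labelled Lo control replicate 3 at -0.0242, so that both were shifted by at least 1.02. That argues against a mixture of RNA from both folate levels, since both arrays lay at least 0.524 from the midpoint. The deviations of the 2 arrays from their groups correlated at r = -0.656 across genes. This argues against a shift shared by replicate 3 as the cause of their places. A smaller shared shift could not show, because arrays lying with opposite folate levels deviate in opposite directions. Exchanged labels of the 2 arrays are a candidate explanation that these values are consistent with, although other handling errors with the same outcome were not tested. No biological explanation was tested.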

How the results depend on the processing

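The fits without both arrays out of place, with and without a block, were chosen after seeing the data; the other settings were not. The counts for pemetrexed in Hi cells stayed at 0 under every setting, and those in control cells at 0 under all but the fits without both arrays, which called 1320, or more with a block. For pemetrexed in Lo cells the 1978 genes became 1262 with no variance moderation, 731 at 1.5-fold or more, 229 at 2-fold or more and 915 at an adjusted p under 0.01. For low folate in treated cells 4107 became 1604 and 502 at those folds and 2176 at the stricter p. For the interaction 886 became 563 with every probe set as a unit, 291 with no moderation, 246 at 2-fold or more and 246 at the stricter p. The fold and p thresholds call fewer genes by construction, and the cause was not tested for the others. Leaving out single arrays gave 1170 to 2563, 2855 to 4607 and 443 to 956 genes for these 3 comparisons, and 0 to 0 for the other 2; where 2 arrays of a group remained the spread was pooled over groups.

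The replicate number as a block gave 0, 2248, 0, 4492 and 994 genes for Hi, Lo, control, treated and interaction contrasts with all 12 arrays, where 9 of 74 named interaction genes, including ATP6V0D2, IL1B, TNFAIP3, IL1RL1 and SERPINB7, lost the call (limma adjusted p = 0.0617, 0.0630, 0.0621, 0.0642 and 0.0507 for these). There the deviations of same-numbered arrays correlated from -0.656 to 0.514, with 11 of 18 pairs above 0.1 and 5 of 12 arrays closest to their own number. The 7 other pairs held an array out of place or joined Hi and Lo controls, and the numbers were not taken to pair all 12 arrays. Without both arrays the numbers were assumed to pair the rest, although arrays numbered 2 and 3 also correlated across numbers (0.171 to 0.439). There the block gave 0, 3385, 2422, 6554 and 1738 genes. It added the calls of 0, 4, 4, 1 and 8 named genes and removed 0; the lists of interferon-stimulated genes in Lo cells and of fibroblast markers in control cells lost the call, and no other list changed.

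Gene lists called for Hi cells numbered 3, against 5 under quantile normalization, 0 with an estimated correlation and 0 with fry, and 1 to 9 when single arrays were left out. For control cells 6 became 10 without both arrays and 0 with an estimated correlation or fry (1 to 10 without single arrays). An estimated correlation left 3 of 12 lists in Lo cells, 2 of 11 in treated cells and 2 of 11 in the interaction. Fry called 14, 14 and 12 lists in these comparisons. Leaving out single arrays gave 11 to 12, 10 to 13 and 10 to 13 lists called by camera. With single arrays left out the camera adjusted p of G2 and mitosis in Hi cells ran from 2.86e-12 to 0.958, with the direction reversed at 0.219 without Hi pemetrexed replicate 1, and that of interferon-stimulated genes in control cells from 1.76e-06 to 0.794, reversed at 0.794 without Lo control replicate 2; the cause was not tested. No named gene changed direction while called under any setting. Median centring or quantile normalization moved no median of all genes by more than 0.1.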

Other observations

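The tests of single segments of chromosomes 3 and 6, and all results without the 2 arrays, were chosen after the result was seen.

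Without the 2 arrays out of place, some members of the fibroblast, prostanoid, purine and folate lists also differed between untreated Lo and Hi cells, while most did not pass the test. Of 15 fibroblast and smooth muscle markers 3 were higher and 0 lower (3 adjusted over the list alone; camera adjusted p = 0.0476, and adjusted p = 0.541 with an estimated correlation): periostin (POSTN, 1.53 ± 0.14), FAP (0.89 ± 0.12) and ACTA2 (0.47 ± 0.11). The list lost its call with the replicate number as a block (camera adjusted p = 0.0598). Their median was 0.00, with a mean of 0.20. LOX, the gene of an enzyme that crosslinks collagen, was higher (1.29 ± 0.16) with ADAMTS1 (1.16 ± 0.13), and the growth factors CCN2 (1.63 ± 0.15) and CCN1 (1.05 ± 0.11) were higher too. Of 20 prostanoid and leukotriene genes 6 were higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.0141, and adjusted p = 0.314 with an estimated correlation), including the prostaglandin receptor PTGER4 (0.56 ± 0.11). Of 16 purine genes 3 were higher (6 adjusted over the list alone; camera adjusted p = 4.74e-05, and adjusted p = 0.285 with an estimated correlation): ADA (0.90 ± 0.09), PPAT (0.48 ± 0.12) and IMPDH2 (0.44 ± 0.11). Of 28 folate genes 3 were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0167, and adjusted p = 0.368 with an estimated correlation), with the proton-coupled folate transporter SLC46A1 (0.42 ± 0.10) higher and the cobalamin carrier TCN2 lower (-0.98 ± 0.09).

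Of 12 complement genes 2 rose and 2 fell in treated Lo cells, as many as adjusted over the list alone, with no shift of the list (camera adjusted p = 0.489). C3 (1.86 ± 0.30) and C1S (0.94 ± 0.12) rose, and C5 (-0.57 ± 0.13) and the inhibitor CD59 (-0.23 ± 0.07) fell. CD59 lost the call without any single array but Hi pemetrexed replicate 3 or the array labelled Hi control replicate 3, and without both arrays out of place (limma adjusted p up to 0.184), though with the replicate number as a block in that last fit it passed (-0.22 ± 0.07, limma adjusted p = 0.0418). In the same cells the angiogenic factor VEGFA rose by 0.85 ± 0.10 and the glycolytic regulator PFKFB3 by 0.72 ± 0.08. The prostacyclin synthase gene PTGIS fell by 0.79 ± 0.11, thrombospondin 1 (THBS1) by 0.45 ± 0.06 and the lung carcinoma marker ALDH1A1 by 1.16 ± 0.14. The 15 leukocyte markers had 1 gene higher, LCP1 (1.11 ± 0.23), and 1 lower, LYZ (-0.81 ± 0.13), with 2 and 1 adjusted over the list alone. The 18 epithelial and lung carcinoma markers had 0 higher and 1 lower (1 adjusted over the list alone).

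Copy number was weighed as an explanation for the 4107 genes that differed between treated Lo and Hi cells, since Lo cells had been adapted as a separate culture. Over 12195 genes with a mean log2 value over 7, the chromosome median farthest from 0 was that of chromosome 12, at 0.0492 in size, which argues against whole chromosomes. Among 1119 windows of 50 neighbouring genes the largest median was 0.617 in size, on chromosome 6, in windows holding up to 34 histone genes, but the same windows differed by at most 0.0698 in untreated cells without the 2 arrays (2 against 2), which argues against copy number there. A window on chromosome 3 from CMSS1 to POGLUT1 had a median of 0.22 in treated and 0.154 in those untreated cells and 0.01 for pemetrexed in Lo cells, so a gain there may contribute, although 100 shuffles of the genes reached 0.266. The windows outside 0.2 held 75 of 3664 called genes. Of the 4107 genes, 1811 also passed for pemetrexed in Lo cells with all arrays, each in the same direction. Both comparisons use the Lo pemetrexed arrays with the same sign. The difference between treated cells thus also holds the response of Lo cells to pemetrexed. Adaptation to low folate stays open for genes outside those windows, and it was not separated from that response.

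Other assignments of the same arrays were tried for each count. With 3 arrays against 3 there are 10 splits, so the share cannot be under 0.1. For pemetrexed in Lo cells 1 of 10 splits, the real one, gave as many genes (1978, highest other 0), and for low folate in treated cells 1 of 10 (4107, highest other 0). For pemetrexed in Hi cells all 10 of 10 gave 0. For low folate in control cells all 10 of 10 gave at least the real count of 0, and 1 other split called 2273 genes, that which sets the array labelled Hi control replicate 3 with Lo controls 1 and 2, which points to a structure of the samples. For the interaction 6 of 100 splits gave at least the real 886 genes, with 1777 in the highest other. Of these 6, 1 was the real assignment, and the other 5 kept the Lo groups as labelled and rearranged Hi arrays. Splits that mixed the Lo groups called 0 genes. Those that kept the Lo groups retain the response of Lo cells, so the share of splits cannot decide whether chance gave this count.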
